A study of Mus musculus with 20 samples.

How the data were processed

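The series measured ribosome footprints and input RNA from the hippocampus of mice that lack Qtrt1, the catalytic subunit of the tRNA-guanine transglycosylase, and of wild-type mice. A ribosome footprint is the stretch of mRNA that a ribosome shields from nuclease, so its counts report which codons ribosomes occupied. Input RNA is the cytoplasmic RNA of the same lysate before nuclease treatment. The labels give separate animals, 10 in all, each with 1 footprint library and 1 input library. Females comprised 3 animals per genotype and males 2 animals per genotype.

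The count table deposited by the authors holds raw whole-number counts per gene symbol for 18054 genes in 20 libraries, without normalization. For each footprint library the authors deposited a table of codon occupancy, in which coverage is given, per the file headers, as counts of footprints per codon of an mRNA. Those tables also carry the single-codon occupancy, which per the file headers is a ratio of a codon's coverage to the mean coverage of the codons of its mRNA, and the covered share of each coding sequence as a percent, also per the file headers. The occupancy tables listed only codons with at least 1 footprint, and the lowest codon position was 15. A further deposited table per footprint library gives the mean enrichment of each of the 61 sense codons as a ratio at 90 positions on either side of a reference codon, where a ratio of 1 means no enrichment. The authors called that enrichment unbiased, and the correction behind the name is not given in the sources used here. The matching deposited tables of SD were not used here, because they describe mRNA positions within a library and not the spread between animals. The submitters' processing notes listed cutadapt 1.8.1, Trimmomatic 0.39, Bowtie 1.0.0, Bowtie 1.2.2 and SAMtools 0.1.19, without role or order. The genome build and the program that counted reads are not given in the sources used here, so no coordinates are printed.

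Footprint totals ran from 5357810 to 15518000 counts per library and input totals from 9000660 to 13637400, each rounded to 6 digits. Counting error alone is small for abundant genes at that depth, and chi-square per degree of freedom between replicate libraries of a group, which is near 1 for counting error alone, ran from 3.55 to 15.0. Averaged over genes, animals of a group thus differed by more than counting error, which was not tested gene by gene. Whether footprint counts were collapsed by molecular identifiers is not given in the sources used here.

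Gene tests used edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter on the 4 groups of sex and genotype, and quasi-likelihood F tests on group means. Knockout was set against wild type in females, in males and as the mean of both sexes. The sex-by-genotype comparison was the female difference minus the male difference. Translational efficiency, the footprint level relative to the input level, was tested as the interaction of assay and genotype in 1 model of all 20 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale, knockout relative to wild type, with a standard error from the fit.

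Fixed gene lists, 39 in all, covered pathways, translation, stress responses and the cell types and neighbouring regions that a hippocampal dissection can hold. They were tested with limma 3.58.1 camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Camera with an estimated correlation and fry were run beside it, and adjusted p values cover all lists within a comparison. Over the 12 comparisons 92 of 468 list tests passed, 50 upward and 42 downward. With an estimated correlation none of the 92 passed, the lowest adjusted p being 0.268, and with fry none passed. Counts are also given adjusted over the list alone.

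Codons read by queuosine tRNAs were AAC, AAT, CAC, CAT, GAC, GAT, TAC and TAT, which encode asparagine, histidine, aspartate and tyrosine. The control set was TTC, TTT, TGC, TGT, AGC and AGT, which share the NNY form and are read by tRNAs without queuosine. Enrichment was compared on the log2 scale, and each set was scored by its mean. Genotype labels were permuted within sex in exact two-sided tests, with 120 assignments for both sexes, 20 for females and 6 for males. The smallest possible p was 0.0167 for both sexes, 0.10 for females and 0.333 for males. Single codons were tested with limma over the 61 codons. The tables name no ribosomal site, and a rule fixed beforehand took the position with the widest spread across codons in wild-type libraries, which was position 1. The SD across codons was 0.631 at position 1, 0.399 at position 0, 0.346 at position 2 and 0.325 at position 3, and at most 0.183 beyond 10 codons. Recomputing the profile from the occupancy tables showed that position 1 is the codon 1 upstream of the codon listed there. Position 1 is therefore not certain to be the A site, where a tRNA is decoded, and position 0 is printed beside it. The P and E site alternatives were taken as positions 2 and 3 once that orientation was known. Between 99.1% and 99.2% of the mRNAs in the occupancy tables matched a coding sequence of the GENCODE mouse annotation, release M21. The recomputed values used 2291 to 3351 mRNAs per library with coverage of at least 50.

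Codon content was the share of queuosine-read codons in a gene's coding sequence of at least 150 bases, related to its fold change by Spearman's rho across genes with an exact permutation of genotype within sex. Genes are not independent replicates, so no p across genes was used.

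The groups, gene lists, tests, thresholds, site rule and the alternatives listed next were set before the data were examined. These alternatives were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no filter, a strict filter at a mean count of 50, a replicate block, the libraries of 1 sex alone, array weights for codons, enrichment on the linear scale, enrichment divided by the median over codons, other positions, recomputed occupancy, and leaving out each animal in turn for genes and codon enrichment. Added after the data were seen were settings without the animals that stood apart in choroid plexus or striatum markers, marker levels as covariates, removal of the trend over GC content, the age of the males as a block, position 0, and leaving out each animal for lists and codon content. Named genes followed a fixed rule. It took Qtrt1 and Qtrt2 always, then the 10 higher and 10 lower called genes with the smallest p whose libraries did not overlap between genotypes, and the 4 members of each called list with the smallest p in its direction. Gene models without an established symbol were counted but not named. A pair of genes that the rule names is not reported here. The 8 queuosine codons were always named, with the 5 other codons of smallest p per comparison. Where fewer than 5 genes passed, the 5 higher and 5 lower genes with the smallest p were added as values that did not pass.

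The labels do not say that a replicate number marks a shared litter, batch or day, so numbers were not taken to pair animals across genotypes. In males the number goes with age, 6 months and 18 days or 5 months and 16 days in both genotypes, so fits with male age as a block were added. Footprint and input of 1 animal do belong together by the labels. Residuals from the group means correlated between both assays of an animal at r of 0.257 to 0.548 across genes. The residuals of the 2 males of a group mirror each other, so both share 1 value of r by construction. A fit with animal as a block is printed beside translational efficiency for that reason.

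The tests were tried on simulated data with the group sizes of the series. Simulated counts varied independently between genes, so differences of an animal shared by many genes were left out. The changed genes were drawn only from those above a floor of mean count, so the rarest genes tested were not among them. The shares recovered may therefore be too high for the real libraries. For genes changed 2-fold, edgeR recovered 79.1% in female footprints, 70.1% in male footprints, 92.5% for both sexes and 52.2% for sex-by-genotype. The figures for input RNA were 95.5%, 85.1%, 97.0% and 73.1%, and for translational efficiency 74.6%, 49.3%, 83.6% and 34.3%. A codon set raised by 0.20 in simulated tables passed in 100% of data sets, and a set left unchanged passed in 3.5%. The simulated noise was independent between codons and alike in all libraries. Real means of the queuosine set had an SD of 0.15 in wild-type and 0.06 in knockout males, and 0.04 and 0.01 in females. The 100% may therefore be too high for the real tables. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for codon tables and plots.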

Results

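Ribosome profiling and matched RNA sequencing were carried out on the hippocampus of mice without Qtrt1, which encodes the catalytic subunit of the enzyme that places queuosine in tRNAs, and of wild-type mice. Queuosine is a modified guanosine whose base comes from diet and gut microbes. It sits in the anticodon of the tRNAs for asparagine, aspartate, histidine and tyrosine. The series title speaks of learning and memory that depend on sex and of elongation speed that depends on codons, so genotypes were compared within each sex and the sexes with each other. Females gave 3 wild-type and 3 knockout animals and males 2 and 2. Footprint libraries held from 5357810 to 15518000 counts and input libraries from 9000660 to 13637400. Females were 6 months and 21 or 22 days old, and males 6 months and 18 days or 5 months and 16 days. The first principal component of the libraries separated the sexes, which thus also differed in age. It carried 34.6% of the variance of footprints and 33.8% of that of input RNA. In input RNA it also set knockout females (at most 3.37) apart from wild-type females (at least 24.9), with males at −28.3 to −12.4.

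Qtrt1 itself was read in every wild-type library and at low counts in every knockout library. Its footprint counts were 40, 28 and 30 in wild-type females against 5, 1 and 4 in knockout females, and 94 and 46 in wild-type males against 10 and 3 in knockout males. Input counts were 88, 88 and 74 in wild-type females against 28, 24 and 28 in knockout females, and 78 and 66 in wild-type males against 29 and 24 in knockout males. Qtrt1 footprints fell by 3.62 ± 0.44 on the log2 scale in females (standard error from edgeR, adjusted p = 0.00543) and Qtrt1 input RNA fell by 1.67 ± 0.18 (adjusted p = 0.00335). The male differences were −2.88 ± 0.46 in footprints and −1.26 ± 0.22 in input RNA and did not pass after adjustment over all genes (adjusted p = 0.23 and 0.373). With both sexes together Qtrt1 fell in footprints by 3.25 ± 0.32 (adjusted p = 0.00102) and in input RNA by 1.47 ± 0.14 (adjusted p = 0.00356), and the female and male differences were not distinguishable (footprint difference −0.74 ± 0.70, adjusted p = 0.823). Qtrt2, the partner subunit, differed by 0.14 ± 0.24 in female footprints (adjusted p = 0.747) and by 0.03 ± 0.28 in male footprints (adjusted p = 0.995), and neither passed. The plot of Qtrt1 levels shows each library.

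**Figure D1:**
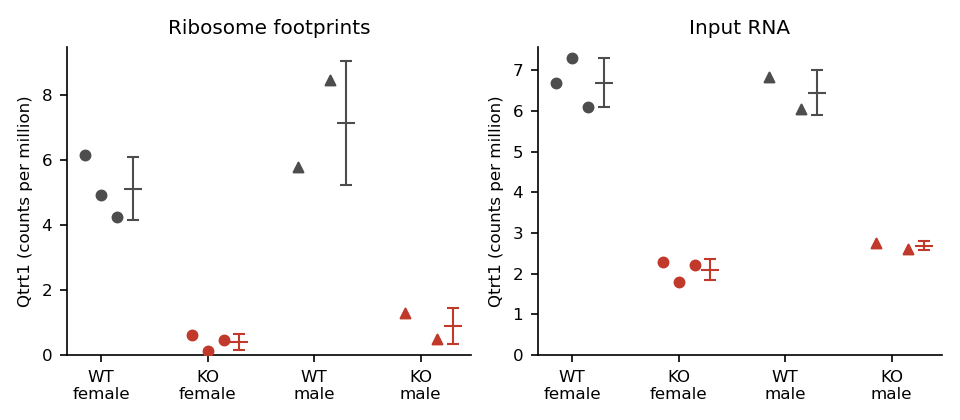
Qtrt1 level in CPM (vertical axis, from 0) in footprint and input libraries of each sex and genotype. Each symbol is 1 animal (circles female, triangles male), and bars give the group mean with 1 SD. Knockout libraries lie below all wild-type libraries of their sex in both assays.

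The codon tables address the question in the series title most directly. At position 1, ribosomes of knockout animals lay more often on codons read by queuosine tRNAs than ribosomes of wild-type animals. The mean log2 enrichment of the 8 codons was 0.10 ± 0.04 (SD, n = 3) in wild-type females and 0.30 ± 0.01 (SD, n = 3) in knockout females, and 0.07 ± 0.15 (SD, n = 2) and 0.24 ± 0.06 (SD, n = 2) in males. The difference was 0.20 in females, 0.18 in males (0.070 without wild-type male 2 and 0.28 without wild-type male 1) and 0.19 with both sexes weighted equally, which is 13.9% higher. All 5 knockout libraries lay above every wild-type library of their sex. The exact two-sided permutation test gave p = 0.0167 for both sexes, the smallest possible value and 0.0222 after adjustment over 8 codon sets. The exact permutation p was 0.10 in females and 0.333 in males, in each case the smallest that the design allows, and 0.90 for the difference between the sexes. For that last p genotype was permuted within each sex, so a shift shared by both sexes widens the values it is compared with. It therefore cannot show that the sexes were alike. The NNY control codons, which share the shape of these codons but have no queuosine tRNA, differed by 0.09 in females, 0.01 in males and 0.05 in both (exact permutation p = 0.15). In females the control set likewise reached the smallest possible exact permutation p of 0.10, with all 3 knockout libraries above every wild-type library. The queuosine set exceeded the control set by 0.14 (exact permutation p = 0.0167). With each library divided by its own median over codons, the queuosine set was 0.11 higher (exact permutation p = 0.0167) and the control set was at −0.02.

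The amino acids differed from each other. Enrichment at tyrosine codons was higher by 0.47 in females and 0.39 in males, 34.5% higher across both sexes. Asparagine codons were higher by 0.25 and 0.29, or 20.6%. Aspartate codons moved the opposite way, with −0.23 in females and −0.12 in males. Each of these amino acids gave the smallest possible p in the exact permutation test across both sexes (p = 0.0167), with every knockout library on the same side of the wild-type libraries of its sex. Histidine codons were higher by 0.30 in females and 0.15 in males without passing (exact permutation p = 0.15), and the male direction rested on wild-type male 2 (−1.62), since wild-type male 1 (−0.97) lay above both knockout males (−1.17 and −1.12). Codons ending in C were higher by 0.25 and codons ending in T by 0.13 over both sexes, and the gap between them of 0.11 passed (exact permutation p = 0.0333) but not once any of 6 animals was left out, among them wild-type male 2 (gap 0.08, exact permutation p = 0.0667).

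Among single codons, TAC for tyrosine rose most, with a mean enrichment of 0.595 ± 0.023 (SD, n = 3) in wild-type and 0.949 ± 0.005 (SD, n = 3) in knockout females, and 0.599 ± 0.073 (SD, n = 2) and 0.871 ± 0.090 (SD, n = 2) in males. The limma test called 6 of 61 codons in females (adjusted p under 0.05), of which AAC (0.41 ± 0.05, adjusted p = 9.1e-04), TAC (0.68 ± 0.08, adjusted p = 9.1e-04), TAT (0.26 ± 0.06, adjusted p = 0.0397) and the serine codon TCC (0.32 ± 0.07, adjusted p = 0.0351) rose. GAC (−0.23 ± 0.05, adjusted p = 0.0385) and GAT (−0.22 ± 0.06, adjusted p = 0.0455) fell. In males AAC (0.36 ± 0.06) and TAC (0.54 ± 0.10) rose, both at adjusted p = 0.0120. Both sexes together gave 4 codons, AAC, TAC and TAT up and GAC down, and no codon differed between the sexes by limma (lowest adjusted p = 0.697, 1 codon at an unadjusted p under 0.05). AAT, CAC and CAT were not called in any of these comparisons. The calls changed when single animals were left out. Without wild-type male 1 they numbered 32 in females, 18 in males and 35 in both sexes. They fell to 0 in males without wild-type male 2 or knockout male 2, and to 2 in females without wild-type female 1 or 2 or any 1 of the knockout females. Leaving out wild-type male 2 gave 32 codons in females and 18 that differed between the sexes. For both sexes the count was 11 without knockout male 1, 7 without wild-type female 3 and 2 without knockout female 1 or 2. Where counts fell, the smaller sample was not told apart from the influence of the animal left out.

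**Figure D2:**
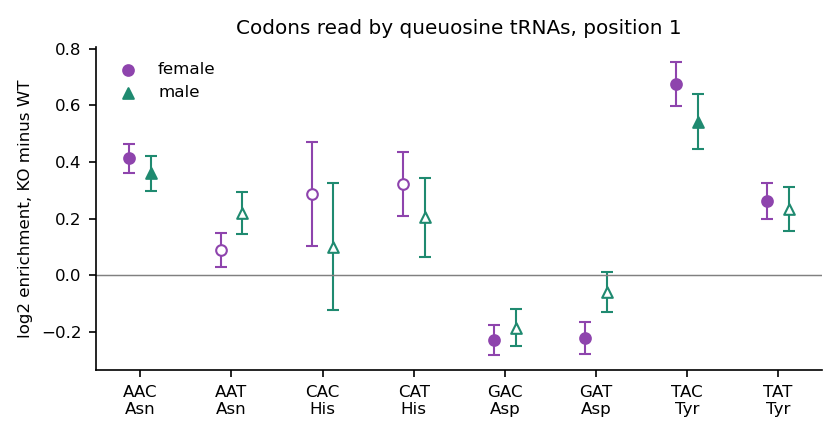
Difference in log2 enrichment at position 1, knockout minus wild type (vertical axis), for the 8 codons read by queuosine tRNAs, with circles for females (n = 3 per genotype) and triangles for males (n = 2 per genotype). Bars are 1 standard error from limma, and filled symbols passed an adjusted p of 0.05. TAC and AAC were higher in both sexes, and GAC and GAT lay below 0.

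The tables leave open whether position 0 is the A site. There the queuosine set was also higher, by 0.10 in females, 0.08 in males and 0.09 in both (exact permutation p = 0.0167). The control codons there differed by 0.07 (exact permutation p = 0.30), and the queuosine set did not exceed them (0.02, exact permutation p = 0.733). Asparagine codons were higher at position 0 by 0.15 and aspartate codons by 0.13 (exact permutation p = 0.0167 each), so that aspartate was lower at position 1 and higher at position 0. Tyrosine codons differed there by 0.05 (exact permutation p = 0.333) and histidine codons by 0.02 (exact permutation p = 0.517). At positions 2 and 3 the queuosine set differed by 0.02 (exact permutation p = 0.40) and 0.04 (exact permutation p = 0.367). The control set was higher at every position from 2 to 7, by 0.040 to 0.066 over both sexes. It was also higher at −1, −6 and −9 (exact permutation p = 0.0333 or 0.0167 at each of these positions, not adjusted over positions). Apart from positions 0 and 1, the queuosine set passed only at position 10, at −0.023 (exact permutation p = 0.0333). The plot of the sets by position shows the peak of the queuosine set at position 1 in both sexes.

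**Figure D3:**
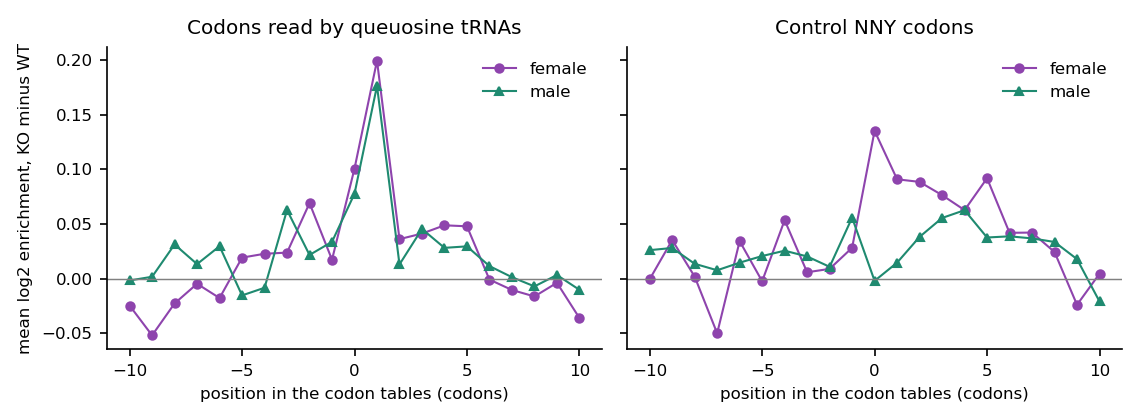
Mean difference in log2 enrichment, knockout minus wild type (vertical axis), of queuosine-read codons and of NNY control codons at positions −10 to 10 of the codon tables (horizontal axis, in codons), with circles for females (n = 3 per genotype) and triangles for males (n = 2 per genotype). The queuosine set reached 0.20 in females and 0.18 in males at position 1.

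In female footprints edgeR called 928 of 13143 genes, 369 higher and 559 lower. Ogn, a matrix proteoglycan of meningeal fibroblasts, rose by 1.25 ± 0.20, the meningeal anion transporter Slc13a4 by 1.04 ± 0.17, the choroid plexus organic anion transporter Slc22a8 by 0.92 ± 0.13 and the selenium carrier Selenop by 0.71 ± 0.11 (edgeR adjusted p between 0.00716 and 0.00965, n = 3 per genotype). Rxfp1, the relaxin receptor, rose by 1.08 ± 0.16 and Nts, which encodes neurotensin, by 1.29 ± 0.22. The sharpest falls were in Tnnc1 (−2.98 ± 0.39) and Myl4 (−3.0 ± 0.41), which encode muscle-type contractile proteins also present in forebrain neurons, and in the cortical marker Lamp5 (−1.32 ± 0.19). The vesicle-priming gene Unc13a fell by 0.71 ± 0.10, the ephrin receptor Ephb6 by 1.18 ± 0.13 (adjusted p = 0.00301) and Exph5 by 1.28 ± 0.16.

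Grouped by the fixed lists, 24 of 24 choroid plexus markers lay higher (median 1.40, adjusted p = 1.15e-07), with 1 called over all genes, Kcnj13 (1.97 ± 0.54), and 10 adjusted over the list alone. Among 19 fibroblast and meningeal markers 7 rose and 1 fell (median 0.62), and 10 rose adjusted over the list alone, including the collagen Col3a1 (1.57 ± 0.29). Reactive gliosis genes had 3 of 18 higher (median 0.43; 9 adjusted over the list alone), among them Gfap (0.57 ± 0.13), the astrocyte filament. Of 17 ependymal markers 1 rose, Cfap126 (1.22), and none adjusted over the list alone. Among 34 immediate early and activity-regulated genes 10 fell and 3 rose (median −0.37; 15 lower and 4 higher adjusted over the list alone), with falls in Arc (−1.16 ± 0.17), Npas4 (−1.0 ± 0.15), Egr4 (−1.38 ± 0.22) and Nptx2 (−0.86 ± 0.17). Postsynaptic genes had 10 of 45 lower (median −0.20; 14 lower and 1 higher adjusted over the list alone), such as the scaffold Shank3 (−0.66 ± 0.14) and the NMDA receptor subunit Grin1 (−0.43). Presynaptic release genes had 5 of 47 lower (median −0.14; 9 adjusted over the list alone), among them Rims3 (−1.17) and Bsn (−0.62). All 14 striatum markers lay lower (median −1.22), 3 of them called over all genes, including Foxp1 (−0.67), and 14 adjusted over the list alone. Camera called these 8 lists, and each call was lost with an estimated correlation (adjusted p = 0.711, and 0.744 for ependymal markers).

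Tissue markers moved with the same animals. The mean choroid plexus marker level in footprints was 1.77, 2.14 and 4.47 log2 CPM in wild-type females against 5.11, 4.90 and 3.78 in knockout females, and 4.76 to 5.27 in males. The transcript for transthyretin, Ttr, ran at 119, 252 and 5675 CPM in wild-type females and 8797, 6696 and 2048 in knockout females. Striatum markers averaged 5.61, 4.38 and 5.46 log2 CPM in wild-type females against 3.50, 4.72 and 3.29 in knockout females, and subiculum and cortex markers 5.61, 5.29 and 5.75 against 5.13, 5.23 and 5.10. Without the wild-type females 1 and 2, which had the lowest choroid plexus levels, 120 genes were called, 89 of them among the 928, and without the 3 females with the highest striatum levels 1 gene was called. Each of these fits leaves 1 wild-type female, whose spread is assumed to match the other groups. With both marker levels as covariates 1 gene was called, in a fit that recovered 14.9% of 2-fold changes in simulated data. The count also changed when single animals were left out. It was 81 without wild-type female 1, 559 without wild-type female 3 and 37 without knockout female 1. It was 218 without knockout female 2 and 555 without knockout female 3. The count was 1521 and 1545 without wild-type males 1 and 2, which enter the estimate of spread. Where it fell, the smaller sample was not told apart from the influence of the animal left out.

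**Figure D4:**
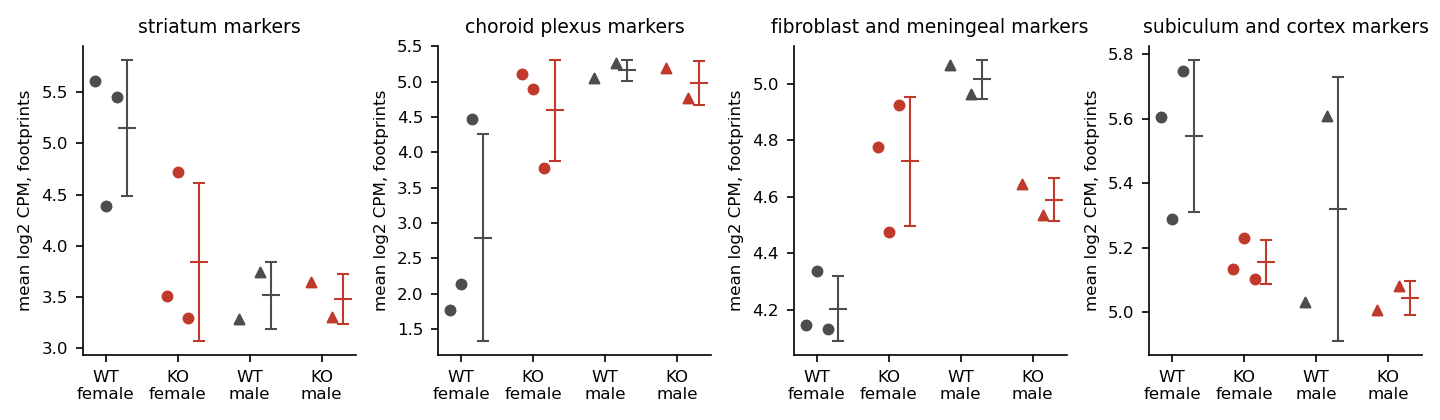
Mean log2 CPM of striatum, choroid plexus, fibroblast and meningeal, and subiculum and cortex markers in footprint libraries (vertical axes, each with its own range) by genotype and sex. Each symbol is 1 animal (circles female, triangles male), and bars give the group mean with 1 SD. Wild-type female choroid plexus levels ran from 1.77 to 4.47 and knockout female levels from 3.78 to 5.11.

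In female input RNA edgeR called 493 of 14164 genes, 106 higher and 387 lower. Gfap rose by 0.72 ± 0.12 (adjusted p = 0.0129), the transcription factor gene Id3 by 0.80, the copper carrier Cp by 0.48 ± 0.09 (adjusted p = 0.0179), Slc13a4 by 0.72 ± 0.13 (adjusted p = 0.0184) and the adhesion gene Tenm3 by 0.46 ± 0.07. Exph5 fell by 1.31 ± 0.11 and Ppp1r9a, which encodes the actin-binding neurabin, by 0.72 ± 0.06, both at adjusted p = 4.9e-04. Ank3, the organiser of the axon initial segment, fell by 0.54 ± 0.07, the GDNF family receptor Gfra2 by 0.95 ± 0.11 (adjusted p = 0.00803) and the kinase gene Prkcb by 0.51 ± 0.07 (adjusted p = 0.0102). Footprint and input calls shared 27 higher genes where 2.93 were expected from independent lists, and 202 lower genes where 16.4 were expected, in libraries made from the same animals.

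Cytosolic ribosomal protein mRNAs lay higher in 75 of 81 (median 0.18, adjusted p = 7.8e-11), with 1 called over all genes, Rps28 (0.34 ± 0.08, adjusted p = 0.0406), and 34 adjusted over the list alone. Nuclear-encoded oxidative phosphorylation had 6 of 79 higher (median 0.15; 20 adjusted over the list alone), for example the complex II gene Sdhd (0.35 ± 0.07) and the complex III gene Uqcr10 (0.40). Mitochondrial ribosomal proteins had 2 of 76 higher over all genes and 2 adjusted over the list alone (median 0.13). Presynaptic genes had 9 of 47 lower (median −0.12; 14 lower and 1 higher adjusted over the list alone), among them Nrxn3 (−0.42) and Pclo (−0.45), and postsynaptic genes 9 of 45 lower (median −0.09; 13 lower and 1 higher adjusted over the list alone), among them Grm3 (−0.66). Immediate early genes had 7 of 34 lower and 1 higher (median −0.13; 13 lower and 5 higher adjusted over the list alone), with Egr1 at −0.91 ± 0.16. Cholesterol synthesis genes tended downward (median −0.076, 19 of 24 below 0). Gliosis genes (2 of 18 called, median 0.38), fibroblast and meningeal markers (5 higher and 1 lower of 18, median 0.59), erythrocyte markers (2 of 11 called, median 0.64), ependymal markers (0 of 18 called, median 0.39), choroid plexus markers (2 of 23 called, median 1.40) and CA1 markers (median 0.33, though its 1 called member fell) tended upward. Striatum markers had 2 of 15 lower (median −1.11; 11 adjusted over the list alone). Endoplasmic reticulum chaperones had a median of 0.13 while the 1 member called fell. Camera called these 15 lists and lost all of them with an estimated correlation (adjusted p between 0.530 and 0.741).

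The same tissue differences ran through the input libraries. Choroid plexus markers averaged 1.36, 1.88 and 3.99 log2 CPM in wild-type females and 4.65, 4.44 and 3.20 in knockout females, and striatum markers 5.36, 4.12 and 5.22 against 3.37, 4.76 and 3.06. Without wild-type females 1 and 2 the count was 498, of which 244 were among the 493, without the 3 high-striatum females it was 7, and with marker covariates it was 0 by edgeR, a fit that recovered 61.2% of 2-fold changes in simulated data. The fits without the low choroid plexus or the high striatum animals leave 1 wild-type female here too. Leaving out single animals gave 46 without wild-type female 1, 1030 without wild-type female 2, 226 without wild-type female 3, 4 without knockout female 1, 162 and 213 without knockout females 2 and 3, and 251 and 252 without knockout males 1 and 2.

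In males no gene passed in either assay with edgeR. Footprints had 562 genes and input RNA 1246 at an unadjusted p under 0.05, and DESeq2 called 1 and 3. Simulated 2-fold changes were recovered at this sample size in 70.1% for footprints and 85.1% for input RNA. Those simulations left out differences of an animal shared by many genes. In the real male footprints even Qtrt1, the gene knocked out, did not pass (edgeR adjusted p = 0.23). The absence of calls in males therefore does not show that genes were unchanged. Among values that did not pass, Cd74 (−0.77 ± 0.17, adjusted p = 0.963) and Spp1 (−0.71 ± 0.17, adjusted p = 0.963) stood lower in footprints, and the astrocyte water channel gene Aqp4 (−0.58 ± 0.09) and Spp1 (−0.93 ± 0.15) in input RNA (both adjusted p = 0.241). Input counts rose to 3 without knockout male 1 and to 15 without wild-type male 1.

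Lists gave more calls in males than single genes. In male footprints camera called 12 lists, none with a called member. Upward were dentate granule markers (median 0.32, 18 of 20 above 0), mitochondrially encoded mRNAs (median 0.48, 9 of 9 above 0, for example mt-Cytb at 0.64 ± 0.25, but a median of 0.12 without wild-type male 2 and 0.076 without knockout male 2, the call being lost in each) and postsynaptic genes (median 0.13). Downward were thalamus markers (median −0.75), fibroblast and meningeal markers (median −0.42), extracellular matrix (median −0.26), oligodendrocytes (median −0.25), subiculum and cortex (median −0.24), oligodendrocyte precursors (median −0.22), myelin (median −0.21), heat shock (median −0.16, 26 of 29 below 0, with Hspa8 at −0.51) and immediate early genes (median −0.15). All were lost with an estimated correlation (adjusted p = 0.808), and 0 members passed adjusted over the list alone. Input RNA gave 4 lists downward, thalamus (median −0.69), fibroblast and meningeal (median −0.31), astrocyte (median −0.16; 3 lower and 1 higher adjusted over the list alone) and heat shock (median −0.11), at an adjusted p = 0.826 with an estimated correlation. Wild-type male 2 had a thalamus marker level of 4.35 log2 CPM in footprints, against 2.96 to 3.59 in the other libraries. Without that animal 6 footprint lists were called, of which 4 were among the 12, and without knockout male 2 there were 7, while input lists numbered 7 without wild-type male 2, 10 without knockout male 1 or wild-type female 2 and 9 without wild-type male 1.

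Over both sexes, Qtrt1 was the only footprint gene that edgeR called, with 2576 genes at an unadjusted p under 0.05 and 528 called by DESeq2. Without wild-type male 1 edgeR called 1453 genes, without wild-type female 2 it called 212, without wild-type female 3 it called 33, without knockout male 1 it called 24 and without knockout female 2 it called 2. With the age of the males as a block, a fit chosen after the data were seen, it called 67. Input RNA gave 104 genes, 13 higher and 91 lower. The activity-regulated Egr4 fell by 0.45 ± 0.07 (adjusted p = 0.0349), Exph5 by 0.86 ± 0.10 (adjusted p = 0.00732), Ppp1r9a by 0.40 ± 0.05 (adjusted p = 0.0113) and the matrix proteoglycan gene Spock1 by 0.48 ± 0.07 (adjusted p = 0.0349). The zinc finger gene Zkscan5 rose by 0.57 ± 0.07 (adjusted p = 0.0113), Tmsb4x, which encodes an actin-binding thymosin, by 0.38 ± 0.06 (adjusted p = 0.0484), and Cst3, which encodes cystatin C, by 0.31 ± 0.06. That input count was 574 without wild-type male 1, 699 without wild-type female 2, 1 without wild-type male 2, 2 without knockout male 2, 4 to 7 without any 1 of the other 6 animals and 219 with the age of the males as a block.

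By list, footprints of both sexes gave 6 camera calls. Immediate early genes (median −0.26; 16 lower and 4 higher adjusted over the list alone), presynaptic genes (median −0.08; 3 lower adjusted over the list alone) and striatum markers (median −0.58) were lower. Dentate granule markers (median 0.37; 5 higher and 1 lower adjusted over the list alone, for example Prox1 at 0.43), mitochondrially encoded mRNAs (median 0.34, the call being lost without wild-type male 2 or knockout male 2) and choroid plexus markers (median 0.65) were higher. No member passed over all genes, and all 6 were lost with an estimated correlation (adjusted p = 0.803). Without knockout male 1 camera called 3 lists, and without wild-type female 2 or knockout female 2 it called 10. In input RNA camera called 13 lists. Cytosolic ribosomal proteins (70 of 81 above 0, median 0.10), oxidative phosphorylation (median 0.08), mitochondrial ribosomal proteins (median 0.06), gliosis (median 0.20), erythrocyte (median 0.40) and choroid plexus markers (median 0.58) were higher. Presynaptic genes (median −0.12; 13 lower adjusted over the list alone), immediate early genes (2 of 34 called lower, Egr4 and Egr1, median −0.14), subiculum and cortex (median −0.32; 1 of 15 called, the cortical transcription factor Tbr1 at −0.56 ± 0.11), thalamus (median −0.32), striatum (median −0.45), GABAergic interneurons (median −0.12) and astrocytes (median −0.09) were lower. Each was lost with an estimated correlation (adjusted p = 0.780), and 7 remained in number without wild-type male 2.

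**Figure D5:**
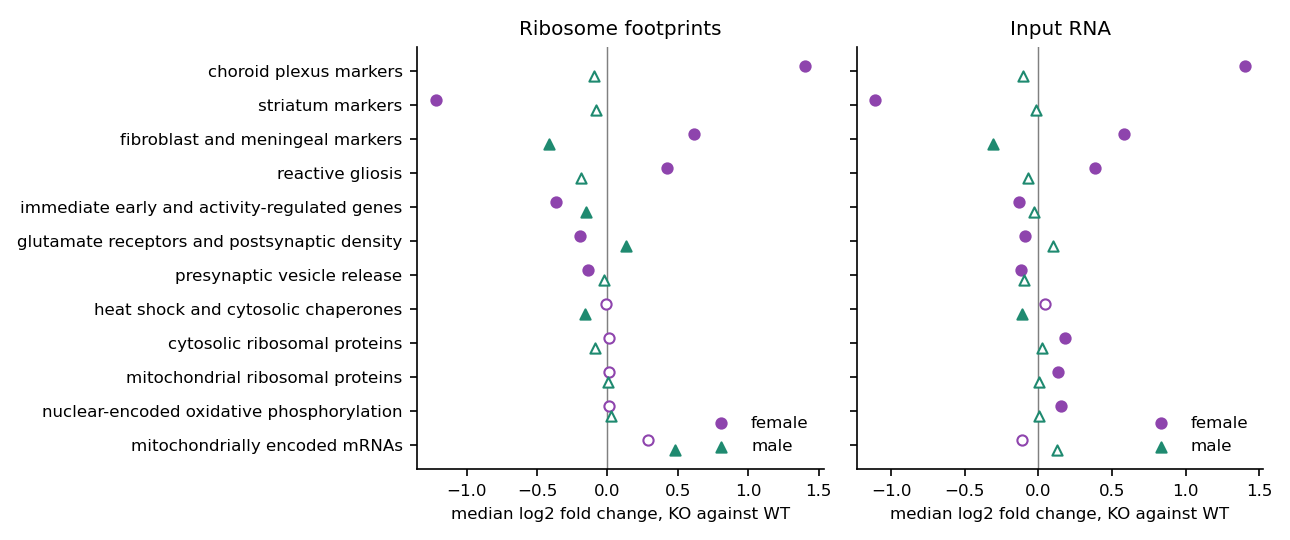
Median log2 fold change of knockout against wild type (horizontal axis) of the members of 12 gene lists in footprints and in input RNA, with circles for females and triangles for males. Filled symbols passed camera at an adjusted p of 0.05 with the preset correlation, and none passed with an estimated correlation. Female choroid plexus markers lay at 1.40 in both assays and female striatum markers at −1.22 and −1.11.

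Whether the sexes differed was tested directly. No gene passed the sex-by-genotype test of edgeR in footprints (1109 at an unadjusted p under 0.05, DESeq2 27, lowest adjusted p = 0.106) or in input RNA (1339 at an unadjusted p under 0.05, DESeq2 63). Without wild-type female 2 edgeR called 10 footprint genes and 40 input genes, and without wild-type male 1 it called 21 input genes. The secreted phosphoprotein gene Spp1 came closest, with a female minus male difference of 1.55 ± 0.22 in footprints (adjusted p = 0.106) and 1.45 ± 0.19 in input RNA (adjusted p = 0.0665). Cd74 differed by 1.38 ± 0.22 (adjusted p = 0.126), Exph5 by −1.69 ± 0.28 (adjusted p = 0.132) and Npas4 by −1.35 ± 0.24 (adjusted p = 0.161) in footprints. Across genes, female and male differences correlated at Pearson r of 0.264 in footprints (Spearman rho 0.323, exact permutation p = 0.133) and 0.127 in input RNA (rho 0.160, exact permutation p = 0.367), and genes are not independent replicates. Of the 928 female footprint genes 703, or 75.8%, had the same sign in males. Camera called 13 lists in footprints and 17 in input RNA as different between the sexes, and none with an estimated correlation (lowest adjusted p = 0.268 and 0.566). In both assays the difference between knockout and wild type was higher in females than in males for fibroblast and meningeal markers, choroid plexus markers and gliosis genes, and lower for striatum markers and postsynaptic genes. Without knockout male 2 there were 7 footprint lists.

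In females the number of genes called for translational efficiency depended on the model, with 6 by edgeR without a block, 394 with animal as a block and 132 by DESeq2. The 6 fell, namely the histone gene H4c9 (−2.16 ± 0.29, adjusted p = 0.00627), the cytochrome oxidase assembly gene Coa3 (−1.16 ± 0.17, adjusted p = 0.0111), Gps1 of the COP9 signalosome (−0.97 ± 0.15, adjusted p = 0.0233), the antizyme gene Oaz2 (−0.86 ± 0.15, adjusted p = 0.0334), the ribosomal stalk gene Rplp0 (−0.71 ± 0.13, adjusted p = 0.0485) and the complex IV gene Cox5b (−0.95 ± 0.17, adjusted p = 0.0485). Of the 394, 189 were higher and 205 lower. The count without a block was 0 without wild-type female 1 or 2 or knockout female 1 or 2, 3 without wild-type female 3, 10 without knockout female 3, 16 and 17 without knockout males 1 and 2, and 21 without wild-type male 1 or 2. Qtrt1 itself differed by −1.94 ± 0.47 in females (adjusted p = 0.137, with the block 0.0328). In males edgeR called none (367 genes at an unadjusted p under 0.05, 1 with the block, the cation channel gene Trpc6 at 1.79, and 1 without knockout male 1). Both sexes together also gave none (1458 at an unadjusted p under 0.05, DESeq2 53, 114 with the block, 167 without wild-type male 1 and 1 without knockout male 1), and neither did sex-by-genotype (409 at an unadjusted p under 0.05, none with the block). Trpc6 differed by 1.41 ± 0.26 over both sexes (adjusted p = 0.0961, with the block 1.48 and adjusted p = 1.5e-04).

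Camera at the preset correlation called 2 lists in female translational efficiency, and lost both with animal as a block, with the age of the males as a block or with an estimated correlation. Oxidative phosphorylation had 1 of 80 members lower over all genes, Cox5b (median −0.13; 8 lower and 1 higher adjusted over the list alone), and mitochondrial ribosomal proteins 0 of 76 (median −0.07; 2 lower adjusted over the list alone). The call of both was at an adjusted p = 0.0385, which became 0.0751 with animal as a block and 0.0543 with male age as a block, and adjusted p = 1.00 and 0.615 with an estimated correlation. The difference between the sexes was also called for both, at medians of −0.11 and −0.17 (adjusted p = 0.00213, with the block 0.0117 and 0.0191, and adjusted p = 0.999 and 0.399 with an estimated correlation). No female list was called without wild-type female 2 or 3 or knockout female 2, 4 were called without wild-type female 1, and the difference between the sexes held for 1 list without wild-type male 2.

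Whether mRNAs rich in queuosine-read codons responded differently was tested across 13087 genes in footprints. Spearman's rho between the share of those codons and the fold change was 0.210 in females, 0.128 in males and 0.209 in both (exact two-sided permutation p = 0.10, 0.667 and 0.25, n = 6, 4 and 10 libraries). The C-ending and T-ending codons of the set went opposite ways. For T-ending codons alone rho was 0.340 in females, 0.227 in males and 0.350 in both, and for C-ending codons alone −0.096, −0.080 and −0.109. None of these passed (exact permutation p of 0.10 or more). For the whole set, the tenth of genes with the lowest share had a median female fold change of −0.14 and the tenth with the highest share 0.13, with 1309 genes in each. In input RNA rho was −0.028 in females and −0.017 in males, and for translational efficiency 0.240 and 0.133 (exact permutation p = 0.15 for both sexes together, rho 0.229). None of 12 relations passed, with adjusted p of 0.6 or more, and without wild-type male 2 the male footprint rho was −0.096. GC content of the coding sequence related to the footprint fold change at rho −0.444 in females and −0.292 in males (exact permutation p = 0.10 and 0.667), and to the input fold change at 0.021 and −0.033. How far the share of these codons follows GC content was not tested.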

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

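The tests of base composition on the female calls, and of read ends, female tissue and codon content on the queuosine codons, were chosen only after those results had been seen. The reading of the tissue tests also changed after a first run, when a share within 1 SD of the 50% bound came to count as undecided. That moved striatum in footprints and choroid plexus in input RNA from excluded to undecided. The tissue test on the queuosine codons was later read with each male left out as well, which moved it from excluded to undecided.

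Among the footprint libraries, 3 values lay far from the others by Dixon's ratio. Wild-type male 1 held about 15518000 counts where the others held 5357810 to 8907360. Wild-type male 2 had a thalamus marker level of 4.35 log2 CPM, with the others at 2.96 to 3.59, and an oligodendrocyte precursor marker level of 5.47, with the others at 5.06 to 5.27. In all 44 groups were listed, and chance alone gives about 1 in 20 of those tested. Qtrt1 levels within a genotype and assay were among the 44 but were not tested, because the critical value used was for 10 libraries.

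Lists whose genotype difference differed between the sexes by the camera interaction test numbered 32, none of them with an estimated correlation. Each value is the median, over the members of a list, of the female minus male difference of each gene. In footprints these were choroid plexus 1.49, fibroblast and meningeal 1.01, thalamus 0.77, ependymal 0.56, gliosis 0.42, interferon response 0.30, extracellular matrix 0.29, endoplasmic reticulum chaperones 0.18, heat shock 0.17, myelin 0.13, presynaptic −0.14, postsynaptic −0.22 and striatum −1.28. In input RNA they were choroid plexus 1.51, fibroblast and meningeal 0.88, thalamus 0.68, gliosis 0.45, erythrocyte 0.41, extracellular matrix 0.27, endoplasmic reticulum chaperones 0.21, endothelial 0.21, integrated stress response 0.18, heat shock 0.17, oxidative phosphorylation 0.14, mitochondrial ribosomal proteins 0.14, cytosolic ribosomal proteins 0.12, astrocyte 0.083, postsynaptic −0.18, mitochondrially encoded mRNAs −0.25 and striatum −1.18. In translational efficiency they were oxidative phosphorylation −0.11 and mitochondrial ribosomal proteins −0.17.

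The female gene calls may owe part of their number to neighbouring tissue taken with the hippocampus in differing amounts. Slopes on marker levels within genotype predicted the sign of 49.3% of the called footprint genes for striatum, 60.3% for choroid plexus and 55.6% for subiculum and cortex, and of 64.8%, 42.4% and 76.8% of the called input genes. Reordering the marker levels within genotype spread those shares with an SD of 16.7, 13.5 and 12.2 in footprints and 19.1, 21.8 and 22.2 in input RNA, so that tissue and genotype cannot be told apart with 3 animals each. Depth as the whole cause was argued against by 69.2% and 73.0% of the calls returning at the depth of the shallowest library. Base composition as the whole cause of the footprint calls was argued against by 56.6% returning without the GC trend. In input RNA 97.4% returned, but the female fold change there hardly followed GC content (Spearman's rho 0.021), so little was removed. Loss of Qtrt1 in the tissue itself stays open.

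Marker levels show how far the animals parted. Drd1 of striatum ran at 95.5, 39.2 and 96.9 footprint CPM in wild-type females, 31.9, 65.4 and 23.6 in knockout females and 15.5 to 18.8 in males, and Lamp5 of cortex at 139, 118 and 196 against 53.5, 65.7 and 62.5. Another list also held 2 of 16 striatum genes, 1 of 24 choroid plexus genes and 3 of 15 subiculum and cortex genes, and 14, 24 and 15 of them passed the count filter in footprints. The filter needs counts in only some libraries, so passing it does not show expression in every animal. The labels name no sort or gate that would remove such cells.

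The higher enrichment of queuosine codons at position 1 was set against 4 technical explanations. Against read-end preference, the set differed by at most 0.039 at the outermost positions, −4 and 5. For codon content, enrichment was recomputed with the coverage expected from the codon share of each mRNA, pooled over mRNAs, and the difference was 0.19. That recomputed profile matched the deposited one at a mean Pearson r of 0.9999. Its result was therefore known beforehand and adds no separate evidence on codon content. Tissue composition of the females stays open, because the male difference was 0.18 beside a female 0.20 but ran from 0.070 without wild-type male 2 to 0.28 without wild-type male 1. Against footprints assigned 1 codon off, a mixture of neighbouring positions predicted 7.07% of the difference of the set, though 67.1% of that of histidine and 34.7% of the fall of aspartate. Slower decoding without queuosine also stays open and is only a hypothesis, since these data also found it, the site behind position 1 stays open, and aspartate moved the other way.

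The lower female translational efficiency of oxidative phosphorylation and mitochondrial ribosomal protein genes was set against 10000 random lists matched on 1 property at a time. The oxidative phosphorylation median lay at percentile 0.24 of lists matched on coding length and 0.03 of lists matched on GC content, which argues against both as the whole cause. The mitochondrial ribosomal protein median lay at percentile 1.65 for GC content but at 11.45 for coding length, so short coding sequences may account for it. Matching on length treats genes as independent, and both calls were lost with animal as a block. An effect of Qtrt1 loss on the footprint level of these genes relative to input in females stays open and was not tested apart from tissue composition. That ratio does not measure elongation speed.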

How the results depend on the processing

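Chosen only after the data were seen were the settings without the animals low in choroid plexus or high in striatum markers, the marker covariates, the removal of the GC trend, the age of the males as a block, position 0, and leaving out animals for lists and codon content, and the tests on them. DESeq2 size factors within edgeR left all 12 gene counts within 1.5 times, and fits on male libraries alone left 3 of 3. Of 246 alternative gene counts 152 stayed within 1.5 times, of 204 list counts 144 did, and of 68 codon counts 40 did. Of 114 alternatives for codon sets 91 kept direction and side of the threshold. Depth limits rare transcripts, such as Qtrt1 in knockouts at 1 to 29 counts. Simulated 2-fold changes in efficiency were recovered at 49.3% in males and 34.3% for sex-by-genotype, and depth was not tested as the reason. Where no reason is given, the cause was not tested.

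For gene counts, the DESeq2 Wald test gave 1, 528 and 27 footprint genes in males, both sexes and sex-by-genotype where edgeR gave 0, 1 and 0, and 3, 409 and 63 input genes where edgeR gave 0, 104 and 0. It gave 132 female and 53 both-sex efficiency genes where edgeR gave 6 and 0. Without a filter the counts were 1, 534 and 23 for the same footprint comparisons, 271 and 1 for both-sex and sex-by-genotype input and 1 for both-sex efficiency. The strict filter gave 29 both-sex footprint and 50 both-sex input genes. The fit on female libraries alone gave 1849 footprint and 72 efficiency genes. Replicate numbers as a block gave 308 female and 2 both-sex footprint genes and 324 female input genes, but the labels do not say that numbers pair animals. Residuals of animals with the same number correlated at −0.12, −0.18 and −0.21 in female footprints, −0.11, −0.21 and −0.21 in female input, −0.08 in male footprints and 0.09 in male input, and no female correlated best with its own number. The animal block, which does pair both assays of an animal, gave 394 female, 1 male and 114 both-sex efficiency genes. The age of the males as a block, 1 column per assay, gave 67 both-sex footprint genes, 219 both-sex and 2 sex-by-genotype input genes and 1 both-sex efficiency gene, and left the 8 other gene counts within 1.5 times.

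Leaving out both low choroid plexus animals gave 120 female, 22 both-sex and 2 sex-by-genotype footprint genes, 401 both-sex and 14 sex-by-genotype input genes and 0 female efficiency genes by edgeR. Without the high striatum animals, which leaves 1 wild-type female whose spread is assumed to match the other groups, edgeR gave 1 female footprint gene, 7 female and 0 both-sex input genes and 0 female efficiency genes. Leaving out the low choroid plexus animals also leaves 1 wild-type female, so the same assumption is made there. Marker covariates gave 1 female and 1 sex-by-genotype footprint gene and 0 female input, both-sex input and female efficiency genes, in a fit with fewer degrees of freedom that recovered 14.9% of simulated 2-fold changes in female footprints and 61.2% in female input. Removing the GC trend gave 107 both-sex and 5 sex-by-genotype footprint genes and 3 female efficiency genes.

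Leaving out 1 animal at a time moved 48 of 120 gene counts by over 1.5 times. Footprint counts ran from 37 to 1545 in females, 1 to 1453 in both sexes and 0 to 10 for sex-by-genotype. Input counts ran from 4 to 1030 in females, 0 to 15 in males, 1 to 699 in both sexes and 0 to 40 for sex-by-genotype. Efficiency counts ran from 0 to 21 in females, 0 to 1 in males and 0 to 167 in both sexes. The lowest female footprint and input counts were without knockout female 1 and the highest both-sex footprint count without wild-type male 1.

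For lists, camera with an estimated correlation and fry each gave 0 calls where the preset correlation gave, for females, males, both sexes and sex-by-genotype, 8, 12, 6 and 13 in footprints and 15, 4, 13 and 17 in input RNA, and 2 each in female and sex-by-genotype efficiency. The animal block and the block on male age each gave 0 female efficiency lists. Marker covariates gave 3 female, 3 both-sex and 8 sex-by-genotype footprint lists, 11 male and 7 both-sex input lists and 4 female and 2 both-sex efficiency lists. Without the low choroid plexus animals there were 10 both-sex and 6 sex-by-genotype footprint lists, 8 male input lists, and 0 female and 3 both-sex efficiency lists. Without the high striatum animals there were 9 male input lists and 1 female and 1 both-sex efficiency list. Leaving out 1 animal gave 6 to 12 male, 3 to 10 both-sex and 7 to 18 sex-by-genotype footprint lists, 4 to 10 male and 7 to 16 both-sex input lists, and 0 to 4 female, 0 to 1 male, 0 to 2 both-sex and 1 to 3 sex-by-genotype efficiency lists.

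Some lists changed direction, by their median or by their test. With marker covariates, which use these same markers, choroid plexus came to 0.043 in female footprints, −0.028 for sex-by-genotype, −0.034 in female input and 0.014 in both-sex input. Striatum came to 0.093 in females, −0.027 in both sexes and −0.069 for sex-by-genotype. Endoplasmic reticulum chaperones came to −0.089 for sex-by-genotype footprints, −0.083 for female input and −0.030 for sex-by-genotype input, erythrocyte markers to −0.019 there, and cholesterol synthesis to 0.0019 in female input. Without the low choroid plexus animals, choroid plexus came to 0.059 in both-sex footprints and 0.094 in both-sex input, myelin to −0.10 for sex-by-genotype footprints and ependymal markers to −0.077 in female input. Without the high striatum animals cholesterol synthesis came to 0.029. Male footprint immediate early genes ran from −0.26 to 0.038, the upper end without wild-type male 2.

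For codon sets, the queuosine set kept its exact permutation p = 0.0167 on the linear scale, divided by the median over codons, recomputed from occupancy and at position 0. At position 0, however, the difference was 0.09, and the set did not exceed the control set (0.02, exact permutation p = 0.733). The recomputed profile nearly repeats the deposited one (mean Pearson r 0.9999), so it is not a separate check. The queuosine set weakened to 0.025 at position 2 and 0.043 at position 3. With the replicate block it stayed at 0.19 while the smallest possible p rose to 0.0625, as for the C-ending minus T-ending gap at 0.11. With males exchanged only within age the exact permutation p was 0.025 for each, the smallest possible of 80 assignments. That gap was 0.0087 on the linear scale, −0.027 at position 2, −0.12 at position 3, −0.012 at position 0 and −0.0082 at position 0 recomputed, and ran from 0.084 to 0.15 without 1 animal. The control set was −0.022 with each library divided by its median over codons, and passed at 0.063 at position 2 and 0.066 at position 3 (exact permutation p = 0.0333 each). The difference between the sexes in the queuosine set was −0.030 on the linear scale, −0.025 with each library divided by its median over codons and −0.0042 at position 3, and ran from −0.083 to 0.13 without 1 animal. The both-sex value itself ran from 0.14 without wild-type male 2 to 0.24 without wild-type male 1.

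Counts of called codons were 19 in females at position 3, 44 with array weights and 2 with the block, 0 in males at positions 0, 2 and 3, with array weights and with the block, and 0, 0, 2 and 2 in both sexes at positions 2 and 3, with array weights and with the block. Without 1 animal they ran from 2 to 32 in females, 0 to 18 in males, 2 to 35 in both sexes and 0 to 18 for sex-by-genotype. Single codons changed sign mainly between positions. At position 2, in females, CAC (−0.025), CAT (−0.22), GAC (0.061) and GAT (0.067) changed sign, in males AAC (−0.14), CAC (−0.026), CAT (−0.059), GAC (0.051) and GAT (0.095), and in both sexes AAC (−0.028), CAC (−0.025), CAT (−0.14), GAC (0.056) and GAT (0.081). At position 3 the codons were AAC (−0.058), CAC (−0.027), GAT (0.14) and TCC (−0.029) in females, AAC (−0.056), CAC (−0.016), GAC (0.011) and GAT (0.12) in males and AAC (−0.057), CAC (−0.021) and GAT (0.13) in both sexes. At position 0 they were CAC (−0.079), GAC (0.055) and GAT (0.15) in females, CAC (−0.039), GAC (0.17), GAT (0.16) and TAT (−0.082) in males and CAC (−0.059), GAC (0.11), GAT (0.15) and TAT (−0.024) in both sexes. Without 1 animal CAC ran from −0.32 to 0.52 in males and −0.016 to 0.40 in both sexes, and CAT from −0.024 to 0.43 in males.

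For codon content, the share of C-ending codons alone turned the sign of rho in footprints, to −0.096 in females, −0.080 in males, −0.11 in both and −0.038 for sex-by-genotype. For efficiency it gave −0.11, −0.027, −0.085 and −0.076, and for input RNA 0.014 in females and 0.045 for sex-by-genotype, while T-ending codons gave 0.023 in male input. Without 1 animal rho ran from −0.096 to 0.22 in male and −0.042 to 0.22 in sex-by-genotype footprints, −0.034 to 0.0061 and −0.025 to 0.0056 in input, and −0.045 to 0.21 in male, 0.14 to 0.26 in both-sex (passing without wild-type male 1) and −0.026 to 0.21 in sex-by-genotype efficiency.

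Of 10352 alternative values for named genes 9120 kept direction and side of the threshold and 48 changed sign. Marker covariates took Cldn2 in female footprints to −0.14, Hspa5 to −0.15 and Pifo to −0.56 for sex-by-genotype footprints, Hbb-bt to −0.028 and Hba-a2 to −0.10 in female input, and Hspa5 to −0.049, Hbb-bt to −0.19, Hbb-bs to −0.21 and Alas2 to −0.019 for sex-by-genotype input. Fam183b came to −0.076 in female footprints without the high striatum animals. Without 1 animal, male footprints ran from −0.91 to 0.031 for Fos and −2.22 to 0.36 for Tcf7l2, both highest without wild-type male 2. The sex-by-genotype difference of Qtrt1 ran from −1.20 to 0.14 in footprints and −0.75 to 0.50 in efficiency, where it was 0.11 without the high striatum animals and 0.31 with covariates. Qtrt2 was called nowhere and changed sign to −0.0077 in male footprints with the replicate block and −0.013 with the age block, to −0.027 in female input without the high striatum animals, to −0.39 in female and −0.085 in both-sex input with covariates, and in both-sex efficiency to −0.0042 without a filter, −0.030 with the animal block, −0.022 with the age block and −0.065 with the GC trend removed. Without 1 animal its footprint values ran from −0.36 to 0.37 in males, −0.11 to 0.26 in both sexes and −0.23 to 0.50 for sex-by-genotype. Its input values ran from −0.061 to 0.18 in females, −0.034 to 0.37 in males and −0.34 to 0.068 for sex-by-genotype, and its efficiency from −0.084 to 0.38 in females, −0.53 to 0.24 in males, −0.20 to 0.19 in both sexes and −0.11 to 0.66 for sex-by-genotype.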

Other observations

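All splits of the animals and the test of position 0 as the A site were tests chosen only after the results had been seen.

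Several lists of translation and stress genes were not called by camera in the footprints of either sex (values are medians). Integrated stress response targets stood at −0.04 in females (1 of 27 called higher, adjusted p = 0.932) and −0.13 in males (adjusted p = 0.121). Cytosolic aminoacyl-tRNA synthetases stood at −0.04 in females (2 of 23 called higher, adjusted p = 0.866) and −0.09 in males (adjusted p = 0.637). Genes of ribosome quality control stood at 0.04 and 0.00 (0 of 24 called in each, adjusted p = 0.866 and 0.880), and initiation and elongation factors at −0.00 in females (4 of 47 called lower, adjusted p = 0.866) and −0.03 in males (adjusted p = 0.694). Endoplasmic reticulum chaperones stood at 0.21 in females (2 of 30 called higher, adjusted p = 0.0824) and −0.02 in males (adjusted p = 0.684). Among 30 genes of queuosine and related tRNA modification, Qtrt1 was the only one called in female footprints (adjusted p = 0.20 for the list).

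Of lists not described above, interferon response genes stood at 0.24 in female footprints (0 of 23 called, adjusted p = 0.0980), microglial markers at 0.06 (1 of 20 called, adjusted p = 0.20) and CA3 markers at −0.23 (2 of 16 called lower, adjusted p = 0.182).

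Other splits of the animals were fitted in the same way. For females there are 10 splits, too few for a share under 0.05. The real split gave 928 footprint genes, 493 input genes, 6 efficiency genes and 6 codons, with 3, 2, 0 and 0 as the highest of the others, and 1 of 10 splits reached the real count in each. For lists the real counts were 8, 15 and 2 with 12, 15 and 4 as the highest others, and 7, 2 and 2 splits reached them.

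For both sexes there are 60 splits. Those for the difference between the sexes also reassign genotype within each sex, so a genotype difference shared by both sexes enters their counts. They do not single out a difference between the sexes. The share of splits that reached the real count was under 0.05 for the 104 input genes (2 of 60 splits, highest other 119), the 4 codons (2 of 60, highest other 41) and, for the difference between the sexes, the 17 input lists (2 of 60, highest other 18). Those shares were not adjusted over the results tested, in each case 1 other split gave more calls, and the gene and codon counts moved without single animals and the lists were lost with an estimated correlation, so chance is not taken as excluded there. The count of 1 footprint gene was reached by 4 of 60 splits (highest other 1148). That gene was Qtrt1, the gene knocked out. The splits compare how many genes were called and not which, so they say nothing about Qtrt1 itself. Chance could not be excluded for the 6 footprint lists (45 of 60, highest other 16) and 13 input lists (12 of 60, highest other 18). For the difference between the sexes the same held for the 13 footprint lists (8 of 60, highest other 16) and the 2 efficiency lists (17 of 60, highest other 4).

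Where the real count was 0, every split reaches it by construction (60 of 60), so the splits say nothing about chance. By edgeR and camera these were the both-sex efficiency genes and lists (highest others 93 and 4), and, for the difference between the sexes, genes in footprints, input RNA and efficiency and, by limma, codons (highest others 1148, 119, 93 and 41).

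The splits that gave 1148 footprint genes, 93 efficiency genes and 41 codons, several times the real counts, were the same one. It kept the females by genotype and set knockout male 1 and wild-type male 2, beside the wild-type females, against wild-type male 1 and knockout male 2, which points to a structure of the male samples other than genotype. The split that gave 119 input genes also kept the females by genotype and parted the males by age, 6 months and 18 days against 5 months and 16 days. With male age as a block edgeR called 219 both-sex input genes, among them all 104, and 67 both-sex footprint genes.

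Position 1, with the widest spread across codons, may be the A site or the P site, and the hypothesis that position 0 is the A site was tested by how far the raised spread reached. Counted from position 0 it reached 5 codons upstream and 4 downstream, and counted from position 1 it reached 4 and 5, at a threshold set after the values were seen. At 1.5 times that threshold the reach was 3 and 1 from position 0 and 2 and 2 from position 1, so the test left both open.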
